A study of Mus musculus with 20 samples.

How the data were processed

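RNA was measured by CEL-Seq, a method that barcodes the 3′ end of polyadenylated transcripts and amplifies them by in vitro transcription before sequencing. Eosinophils and macrophages were isolated by flow cytometry after enzymatic digestion of colons of C57BL/6 mice, per the labels' protocols. The colons came from naive mice or from mice that carried tumors after an induction that the labels call CAC. RNA was extracted with Trizol, and each sample was prepared as 3 technical replicates with different primer pools, per the labels' protocols. How the technical replicates were combined, whether molecular barcodes were collapsed, and the sorting markers are not given in the sources used here.

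The submitters' processing notes name FastQC 0.11.5, Trim Galore, TopHat2 2.1.0, Bowtie2 2.2.6, HTSeq 0.6.1 and DESeq2 1.14.1, with the mouse build GRCm38.p5. The order, the settings and the gene annotation are not given in the sources used here, nor is whether counting used the strand or how reads shared by near-identical genes were assigned. Values of near-identical copies such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Ear1 and Ear2, and the Ifit3, Gbp2 and Mcpt relatives are therefore uncertain for each copy, as are those of overlapping or antisense genes.

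The authors deposited 1 table per cell type, with 50600 gene names and a normalised signal of gene read counts in 2 decimals for each library. In every library the deposited values were whole multiples of what 1 read was worth there. All non-zero values (100.0% in each of the 20 libraries, 374526 values in all) came out whole within 0.1 read when divided by that step. The read counts, and with them the depth and the authors' size factors, were recovered in this way. The factors deviated from median-of-ratios size factors, recomputed within each table, by −1.74 to 2.37% for eosinophils (11891 genes) and by −0.76 to 0.62% for macrophages (12835 genes). Recovered depth ran from 1477255 to 8520874 reads per library. Since each table had been scaled on its own, levels in eosinophils and macrophages were compared only after joint scaling. Of the gene names, 94.3% matched a symbol of GENCODE M21 (GRCm38), the source of the coordinates. Bare numbers stand in place of a name for 27 entries of each file, which are not named in the text. They held at most 0.1323% of a library's reads. A further 187 entries carry 93 repeated names.

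The plan, written before the data were examined, was edgeR's quasi-likelihood test for counts, with limma on a log scale in its place if the tables held normalised values. Because the tables held normalised values, the limma test is the main result. Values were transformed as log2(value + 1), genes were kept when they reached 10 in at least 2 eosinophil libraries or 5 macrophage libraries (the size of the smaller group), and limma 3.58.1 (eBayes with a trend, two-sided) was fitted in R 4.3.3 for each cell type alone with a mean per group. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and genes with an adjusted p under 0.05 are called. Fold changes are on the log2(value + 1) scale, which understates the change of low genes and depends on the pseudocount where a group holds few reads. To test whether the tumor effect differed between cell types, the recovered reads of all 20 libraries were scaled together by TMM factors (edgeR 4.0.16), filtered at 10 in at least 2 libraries and fitted in 1 limma model, with the eosinophil effect minus the macrophage effect as the contrast. edgeR's quasi-likelihood test on the recovered reads, an alternative added after the values were seen, called 505 genes in eosinophils, 2051 in macrophages and 599 for the difference.

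The gene lists, 34 in number, were fixed before the data were examined. They cover markers of the cell types a colonic sort could hold (eosinophil identity, macrophage identity, resident colonic macrophage, monocyte, neutrophil, epithelium, T and NK cell, B and plasma cell, dendritic cell, mast cell, stroma and endothelium, erythrocyte), eosinophil granule proteins, interferon, antigen presentation, inflammatory, metabolic, stress and tissue remodelling programmes. Each list with at least 3 measured members was tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists of that comparison. Camera with a correlation estimated per list and fry, from the same package, were alternatives. The adjusted p of a list is camera's with the preset correlation unless an estimated correlation is named. Calls within a list are given over all genes tested and, where so stated, adjusted over the list alone.

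The choices made before the data were examined were the groups, the tests with their fallback, the alternatives marked as planned, the lists and the rule for the genes named. That rule takes, per cell type, the 8 called genes in each direction with the smallest p among symbols that are not predicted genes, pseudogenes or ribosomal proteins and that reach a group mean of 20. It adds up to 4 members per list by smallest p, Siglecf, Ccr3, Epx and Prg2 in eosinophils, Adgre1, Csf1r, Cx3cr1 and C1qa in macrophages, and the 8 genes with the smallest p for the difference between cell types. The text names the list members in full for lists that pass their test and fewer elsewhere, apart from 2 genes that are not reported here. Genes named outside this rule are said to be so where they appear.

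The tests were checked on simulated data drawn from the real libraries' means and depths with known changes. In the eosinophil design (13280 genes) limma recovered 2.2% of 2-fold and 16.5% of 4-fold changes. In the macrophage design (12226 genes) it recovered 38.1% of 2-fold and 88.2% of 4-fold changes, and for the difference (14955 genes) 1% and 19.1%. False calls made up 5.6%, 4% and 5% of its calls in the 3 designs. In the eosinophil design they made up 41.1% with DESeq2 1.42.0, 20% with edgeR and 19% with limma-voom. The shares for limma in the eosinophil design and for the difference each rested on 1 false call. Each simulated gene had 1 mean level over all libraries apart from its known change. Genes nearly absent from 1 cell type were therefore not represented. Of 40 unchanged simulated lists per design, camera called 0. The simulated genes were drawn independently, so these lists held no correlation between genes. They cannot show how often camera calls unchanged lists of correlated genes.

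The labels number the libraries within each group. Nothing in the labels says that libraries came from separate animals or pools, so p-values measure only the spread between these samples, which may in part be technical. All pairs of libraries of a group differed by more than sampling noise (chi-square per degree of freedom of 8 or more over genes with 50 or more reads), which separate preparations of 1 animal or pool would do too. Each library was treated as 1 replicate. Alternatives covered the scaling (RLE, upper-quartile, TMM, library size alone, factors without mitochondrial and immunoglobulin genes), the pseudocount (0.1 and 10), the filter (none, or 50), the tool (DESeq2, edgeR, limma-voom with quality weights), a change of at least 2-fold, the replicate number as a block, 1 fit over the 4 groups, an epithelial covariate, and leaving out each library or sets of libraries. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 was used to recover reads, to run the tests of the closing section and to draw the figures.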

Results

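The transcripts of eosinophils, granulocytes that reside in the healthy gut wall, and of macrophages, its resident phagocytes, were compared between naive mouse colon and colonic tumors. There were 20 libraries in 4 groups: 2 of eosinophils from naive colon, 7 of eosinophils from tumors, 5 of macrophages from naive colon and 6 of macrophages from tumors. Depth was 4452513 and 7469714 recovered reads in the naive eosinophil libraries and 1978466 to 8520874 in tumor eosinophils. It was 1477255 to 7945096 in naive and 2289383 to 7636153 in tumor macrophages. Between 16282 and 20948 genes had a read in a library.

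Each sort carried more transcripts of its own cell type than the other sort did. Members of the eosinophil identity list summed to 8490 ± 84.5 CPM (SD, n = 2) in naive and 6010 ± 3860 (n = 7) in tumor eosinophils, against 1220 ± 262 (n = 5) and 1630 ± 271 (n = 6) in naive and tumor macrophages. Members of the macrophage identity list summed to 25700 ± 2900 and 30500 ± 4740 CPM in naive and tumor macrophages, against 1490 ± 177 and 1790 ± 260 in the eosinophil groups. Genes on the lists of other cell types were present too. Members of the neutrophil list summed to 9320 ± 3520 CPM in naive and 10400 ± 4070 in tumor eosinophils. The sum was 535 ± 82.8 and 1250 ± 364 in naive and tumor macrophages. Naive eosinophil library 1 had 6840 CPM of it against 8430 of the eosinophil identity list, and library 2 had 11800 against 8550. In naive eosinophils 1 member, Retnlg (named after its values were seen), made up most of the sum, and 3 of 16 members reached 100 CPM. B and plasma cell genes summed to 53300 ± 22300 and 32400 ± 24700 CPM in naive and tumor macrophages and to 6050 ± 2210 and 12100 ± 4130 in naive and tumor eosinophils. Epithelial genes summed to 2520 ± 888, 4230 ± 1820, 1740 ± 1480 and 2110 ± 422 CPM in naive eosinophils, tumor eosinophils, naive macrophages and tumor macrophages. Mitochondrially encoded transcripts took 21.2 ± 4.7% of reads in naive and 24.15 ± 8.28% in tumor eosinophils, where libraries 2 and 3 reached 34.92 and 35.15%, and 11.38 ± 3.18% and 9.52 ± 0.81% in naive and tumor macrophages.

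In tumor eosinophils the interferon response and MHC class II lists were called higher than in those from naive colon, and the immediate-early list and receptors that define the eosinophil were called lower. Of these lists, the immediate-early one was called with an estimated correlation as well. Lrg1 encodes a secreted glycoprotein of the inflammatory response (chromosome 17, 56119678 to 56122001, GRCm38). It rose from 68.1 ± 19.4 normalised reads (SD, n = 2) to 2190 ± 740 (n = 7). Its log2 change was 4.93 ± 0.39 (SE), with an adjusted p of 0.000119 by limma. Saa3, an acute-phase protein, rose from 98.5 ± 21.2 to 1770 ± 485 (log2 change 4.12 ± 0.33, adjusted p = 0.000119). Lrg1 and Saa3 were called higher in tumor macrophages too (log2 changes 3.94 and 3.5). Jund, a subunit of the AP-1 transcription factor, fell from 52300 ± 16100 to 8950 ± 2760 (−2.56 ± 0.35, adjusted p = 0.00271). Siglecf, the surface lectin used to recognise mouse eosinophils (chromosome 7, 43351341 to 43359531), fell from 1590 ± 1020 to 402 ± 133 (−1.89 ± 0.42, adjusted p = 0.0249).

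Of 12984 genes tested in eosinophils, 314 were called higher and 287 lower in tumors, 601 in all, and 2557 had an unadjusted p under 0.05. Among the genes with the smallest p, the neutrophil-attracting chemokine Cxcl5 rose by 4.28 ± 0.42 on the log2 scale (adjusted p = 0.000703). The inflammasome sensor Nlrp3 rose by 4.32 ± 0.44 (adjusted p = 0.000905) and the iron-sequestering Lcn2 by 4.50 ± 0.47 (adjusted p = 0.000917). The copper-binding acute-phase protein Cp (3.82 ± 0.41), the nucleotidase Entpd3 (3.93 ± 0.43) and the keratin Krt6a (4.30 ± 0.48) each had an adjusted p of 0.00111. The phosphatase Dusp1 (−2.36 ± 0.29, adjusted p = 0.00153) and the AP-1 subunit Fos (−2.05 ± 0.26, adjusted p = 0.00185) fell. So did Baiap2 (−2.40 ± 0.32), the kinase subunit Camk2g (−2.24 ± 0.30), Tbc1d8 (−2.24 ± 0.31), the secreted ligand Wnt11 (−3.80 ± 0.54) and the chaperone Dnaja1 (−1.84 ± 0.26). Their adjusted p-values were 0.00257 to 0.0034. When naive library 2 was left out, Jund, Tbc1d8, Wnt11 and Dnaja1 were not called (−2.24, −1.72, −3.87 and −1.77; adjusted p = 0.0507 to 0.0642). Entpd3 was not called with limma-voom (4.2, adjusted p = 0.085). For all 60 called genes that the naming rule gave in eosinophils, the 7 tumor libraries lay on 1 side of both naive libraries. Chance gives this separation to a gene in 5.56% of cases, but these genes were chosen by their p, so the count is no test.

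**Figure D1:**
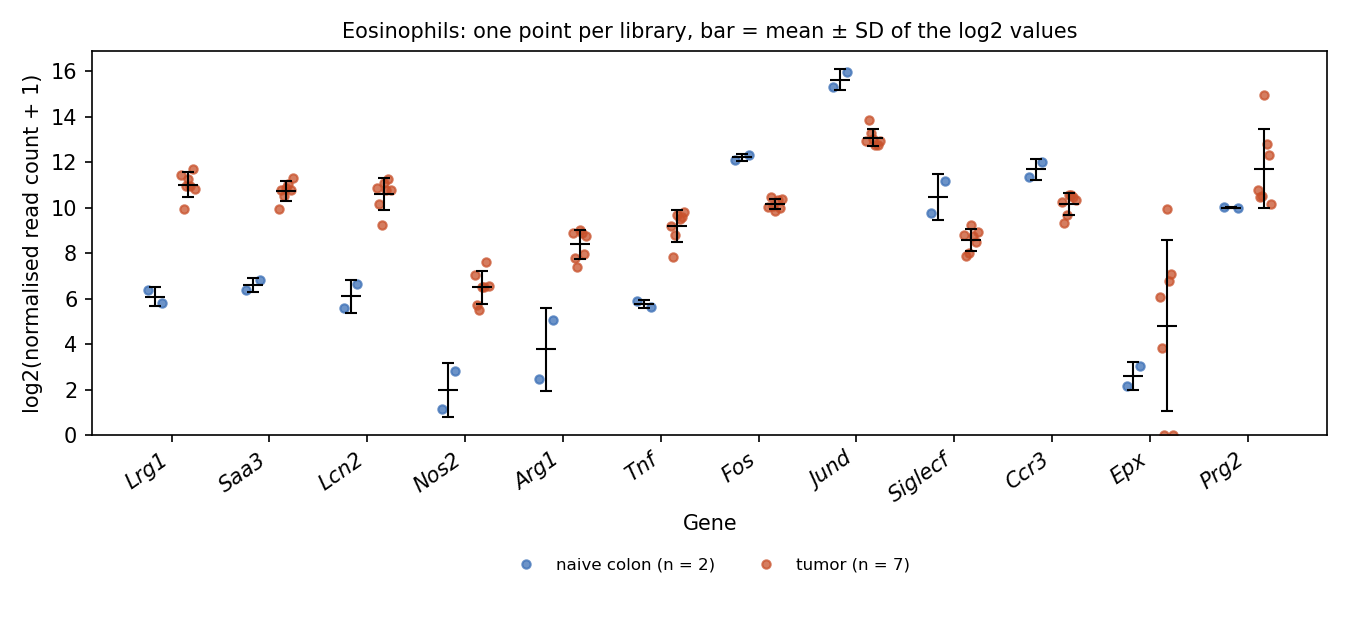
Normalised read counts of 12 genes in eosinophils, as log2(value + 1) on the vertical axis, with 1 point per library and bars for the mean and SD of the log2 values (2 naive and 7 tumor libraries). Lrg1, Saa3, Lcn2, Nos2, Arg1 and Tnf lie higher and Fos, Jund, Siglecf and Ccr3 lower in all 7 tumor libraries than in both naive libraries, while Epx and Prg2 spread widely among the tumor libraries and were not called.

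Part of the interferon and antigen presentation lists was higher in tumor eosinophils. Of the interferon-gamma response list, 10 of 27 measured members rose, 0 fell and 17 were not called (21 higher and 1 lower when adjusted over the list alone). The median log2 change was 2.01, with an adjusted p of 3.59e-12, and adjusted p = 0.293 with an estimated correlation. They included Nos2, the inducible nitric oxide synthase (4.54 ± 0.57, from 3.60 ± 3.45 to 99.5 ± 50.4), the GTPases Gbp3 (3.20 ± 0.53) and Irgm2 (3.46 ± 0.76) and the T cell chemokine Cxcl9 (2.77 ± 0.50). Of the type I interferon list, 6 of 23 members rose, 0 fell and 17 were not called (16 and 0 adjusted over the list alone). For type I interferon genes the median was 1.77 (adjusted p = 2.94e-11, and adjusted p = 0.276 with an estimated correlation). Examples were Ifitm3 (2.30 ± 0.31), Ifit1 (3.12 ± 0.43), Ifit3b (3.26 ± 0.53) and Irf9 (1.72 ± 0.37). Of the MHC class II list, 7 of 13 members rose, 0 fell and 6 were not called (9 and 0 adjusted over the list alone). For MHC class II genes the median was 1.89 (adjusted p = 6.76e-07, and adjusted p = 0.276 with an estimated correlation). H2-DMa rose by 2.39 ± 0.35, H2-Eb1 by 1.89 ± 0.33, the invariant chain Cd74 by 2.07 ± 0.38 and the protease Ctss by 1.80 ± 0.36. Cd74 stood at 15000 ± 3830 normalised reads in tumor eosinophils, and abundant macrophage transcripts rose beside it: C1qb, a complement component, by 2.1 ± 0.43 and C1qc by 1.94 ± 0.42. Of the MHC class I list, 1 of 16 members rose, the activator Nlrc5 (2.19 ± 0.57, adjusted p = 0.0471), 0 fell and 15 were not called, the same when adjusted over the list alone (median 0.72; adjusted p = 0.00456, and adjusted p = 0.564 with an estimated correlation). Without naive library 2, calls held for Nos2, Ifitm3 and Ifit3b. They ended for Gbp3, Irgm2, Cxcl9, Ifit1 and Irf9 (2.90, 3.58, 2.80, 3.16 and 1.20), for H2-DMa, H2-Eb1, Cd74 and Ctss (1.82, 1.43, 1.5 and 2.2) and for Nlrc5 (2.54), with adjusted p-values of 0.0511 to 0.347. Without naive library 1 those of Irgm2, Ctss and Nlrc5 ended (3.34, 1.39 and 1.85; adjusted p = 0.0998 to 0.202). Nlrc5 also missed the threshold without tumor library 1, 4, 5, 6 or 7 (adjusted p = 0.053 to 0.0759). With limma-voom and quality weights in place of limma, Nos2, Ifit3b, Gbp3, Irgm2, Cxcl9, Irf9, Ctss and Nlrc5 were not called (adjusted p = 0.0655 to 0.51). Tap1, a subunit of the peptide transporter, had a log2 change of 1.82 and was not called.

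Part of the neutrophil, macrophage identity, chemokine and NF-kB lists was higher as well. Of the neutrophil list, 6 of 16 members rose, 0 fell and 10 were not called (11 and 0 adjusted over the list alone). For neutrophil genes the median was 2.62 (adjusted p = 7.97e-09, and adjusted p = 0.293 with an estimated correlation). Lcn2, lactoferrin Ltf (4.62 ± 0.65) and the calprotectin subunits S100a9 (4.37 ± 0.64) and S100a8 (4.42 ± 0.71) led it. Retnlg, its most abundant member and chosen after its values were seen, had a log2 change of −0.35 (adjusted p = 0.742). The summed level of the list, given above, did not differ beyond its spread, but in naive eosinophils Retnlg made up most of it. Of the macrophage identity list, 5 of 16 members rose, 1 fell and 10 were not called (9 and 2 adjusted over the list alone). For macrophage identity genes the median was 1.32 (adjusted p = 0.00103, and adjusted p = 0.276 with an estimated correlation). Cd14, the lipopolysaccharide co-receptor, rose by 3.89 ± 0.53, lysozyme Lyz2 by 2 ± 0.37 and the lipid carrier Apoe by 1.93 ± 0.38. Adgre1, which encodes F4/80 and is carried by eosinophils too, changed by −2.20 ± 0.40. Of the chemokine and cytokine list, 6 of 29 members rose, 0 fell and 23 were not called (11 and 4 adjusted over the list alone). For chemokine and cytokine genes the median was 1.26 (adjusted p = 0.00203, and adjusted p = 0.513 with an estimated correlation). Examples were Tnf at 3.43 ± 0.45 (53.4 ± 7.28 to 635 ± 236), the neutrophil-attracting Cxcl1 at 2.08 ± 0.41 and Ccl4 at 2.22 ± 0.50. Cxcl16 of this list (2.02, named after its values were seen) is among the macrophage-specific transcripts of the closing section. Macrophage RNA stays open for it. Of the NF-kB and TNF list, 5 of 28 members rose, 1 fell and 22 were not called (11 and 5 adjusted over the list alone). For NF-kB and TNF genes the median was 1.07 (adjusted p = 0.00543, and adjusted p = 0.593 with an estimated correlation). Ier3 rose by 2.17 ± 0.30, and Tnfaip3, which restrains NF-kB, changed by −1.32 ± 0.30. Without naive library 2, calls ended for S100a8, Lyz2, Apoe and Adgre1 (4.93, 1.84, 1.54 and −1.55) and for Tnf, Cxcl1, Ccl4, Ier3 and Tnfaip3 (3.30, 1.46, 2.52, 1.80 and −1.04), with adjusted p-values of 0.0512 to 0.314. Without naive library 1 they ended for S100a8 and Ccl4 (3.92 and 1.91), for the chemokine list (median 1.12, adjusted p = 0.0881) and for the NF-kB list (0.82, adjusted p = 0.322). With limma-voom, Ltf, S100a8, Lyz2, Apoe, Cxcl1, Ccl4 and Tnfaip3 were not called (adjusted p = 0.0513 to 0.119).

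Of the tumor-associated macrophage list, 8 of 19 members rose, 1 fell and 10 were not called in eosinophils (9 and 3 adjusted over the list alone). Those that rose included Apoe, which the lipid and lysosome list holds too, and Hmox1 (named after its values were seen). Both are among the macrophage-specific transcripts of the closing section, so macrophage RNA in the eosinophil libraries stays open for them. For the other members of these 2 lists that rose, the rise was not set against the tumor macrophage level. Macrophage RNA was therefore not tested for them. For tumor-associated macrophage genes the median was 0.81 (adjusted p = 0.00983, and adjusted p = 0.276 with an estimated correlation). Arg1, the arginine-degrading enzyme, rose from 18.6 ± 19.8 to 362 ± 144 (4.61 ± 0.60, adjusted p = 0.00231), the activin subunit Inhba by 3.89 ± 0.62 and the fatty acid carrier Fabp5 by 2.82 ± 0.48. Vegfa, the angiogenic growth factor, fell from 4610 ± 2890 to 1020 ± 297 (−2.06 ± 0.38, adjusted p = 0.0114). Of the immune checkpoint list, 4 of 17 members rose, 1 fell and 12 were not called (9 and 2 adjusted over the list alone). For immune checkpoint genes the median was 1.15 (adjusted p = 0.0153, and adjusted p = 0.483 with an estimated correlation). Besides Arg1, Pvr (1.55 ± 0.33) and the PD-1 ligand Pdcd1lg2 (2.74 ± 0.63) rose, and Vsir changed by −1.42 ± 0.33. Of the lipid and lysosome list, 5 of 21 members rose, 0 fell and 16 were not called (6 and 0 adjusted over the list alone). For lipid and lysosome genes the median was 0.24 (adjusted p = 0.0109, and adjusted p = 0.294 with an estimated correlation). Examples were the cholesterol exporter Abca1 at 2.54 ± 0.30 and the protease Ctsb at 1.32 ± 0.31. Ribosomal protein genes had 4 of 32 members higher, 0 lower and 28 not called (13 and 0 adjusted over the list alone). Their median was 0.61 (adjusted p = 1.6e-08, and adjusted p = 0.276 with an estimated correlation). Rpl19, Rps19, Rps14 and Rps27 stood at 1.37, 1.31, 1.44 and 1.22. Of the cell cycle list, 1 of 20 members rose, the proliferation marker Mki67 (1.38 ± 0.34, adjusted p = 0.0352), and 19 were not called, Ube2c, Ccna2 and Top2a among them, the same when adjusted over the list alone (median 0.80; adjusted p = 0.00692, and adjusted p = 0.564 with an estimated correlation). Of the oxidative phosphorylation list 0 of 33 members were called by limma, also when adjusted over the list alone (median 0.30; adjusted p = 0.0209, and adjusted p = 0.564 with an estimated correlation). Its leading members Cycs, Uqcrq, Cox8a and Uqcrc1 had log2 changes of 0.89, 0.78, 0.84 and 0.93.

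Arg1 and Abca1 were called with either naive library left out. Without naive library 2, calls ended for Inhba, Fabp5, Vegfa and Ctsb (2.72, 2.94, −1.38 and 1.01), for Pvr, Pdcd1lg2 and Vsir (1.84, 3.63 and −1.61), for Mki67 (1.58) and for Rpl19, Rps19, Rps14 and Rps27 (0.85, 0.73, 0.60 and 0.84), with adjusted p-values of 0.0795 to 0.591. The lipid and lysosome list was not called without it (median 0.07, adjusted p = 0.08). Without naive library 1, calls ended for Pvr, Pdcd1lg2, Vsir and Mki67 (1.26, 1.84, −1.23 and 1.18; adjusted p = 0.0879 to 0.185). They also ended for the tumor-associated macrophage list (median 1.27, adjusted p = 0.0961), the cell cycle list (0.5, adjusted p = 0.322) and the oxidative phosphorylation list (0.18, adjusted p = 0.173). The last was not called without tumor library 1 (0.23, adjusted p = 0.0556) or 2 (0.21, adjusted p = 0.0649) either. Ctsb, Mki67, Rps19, Rps14 and Rps27 also missed the threshold without single tumor libraries (adjusted p = 0.0504 to 0.0827). With limma-voom, Inhba, Fabp5, Pvr, Pdcd1lg2, Vsir, Ctsb, Mki67, Rps19, Rps14 and Rps27 were not called (adjusted p = 0.0677 to 0.332).

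The immediate-early and dissociation list, made of genes that respond within minutes to stimuli that include tissue digestion, was lower in tumor eosinophils. Of its 24 measured members 16 fell, 1 rose and 7 were not called (19 lower and 1 higher when adjusted over the list alone; median −1.38; adjusted p = 3.57e-14), and its call also held with an estimated correlation (adjusted p = 0.0148), which the other lists' calls in eosinophils did not. Fosb fell from 28700 ± 15100 to 4600 ± 1850 (−2.63 ± 0.43), and was not called without naive library 1 (−2.06, adjusted p = 0.0565). Whether naive and tumor tissue were digested and sorted on the same days is not given in the sources used here, so for this list handling and group cannot be separated.

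The eosinophil identity list was called lower in tumor eosinophils, 4 of its members among the genes that fell, while the granule protein list was called higher as a set. Of the identity list, 4 of 17 members fell, 0 rose and 13 were not called (10 lower and 4 higher when adjusted over the list alone; adjusted p = 0.0129, and adjusted p = 0.593 with an estimated correlation). Its median log2 change of −1.18 and its test pointed down while its mean was 0.17. All 6 measured granule protein genes belong to this list too and were its only members with a positive log2 change. Besides Siglecf, the receptor for interleukin-5 Il5ra (−1.82 ± 0.42, adjusted p = 0.03), the eotaxin receptor Ccr3 (−1.52 ± 0.36, adjusted p = 0.0307) and Cd24a (−1.28 ± 0.32, adjusted p = 0.0379) fell. Once naive library 2 was left out, none of the 4 was called (Siglecf −1.19, Il5ra −1.40, Ccr3 −1.18 and Cd24a −1.20; adjusted p = 0.33 to 0.433), nor was Cd24a without naive library 1 (−1.37, adjusted p = 0.0823). Without tumor library 1, Il5ra, Ccr3 and Cd24a missed the threshold (adjusted p = 0.0535, 0.0532 and 0.058), and Cd24a did so without tumor library 3, 5, 6 or 7 too (adjusted p = 0.0554 to 0.0656). Nor was any of the 4 called with limma-voom (adjusted p = 0.0614 to 0.0871), or Ccr3 in eosinophils with 1 fit over all 4 groups (−1.55, adjusted p = 0.167). Of the granule protein list, 0 of 6 members were called by limma (2 higher when adjusted over the list alone), although the list was called higher (median 2.83; adjusted p = 0.00543, and adjusted p = 0.483 with an estimated correlation). Without naive library 1 the list was not called (median 1.86, adjusted p = 0.0961). Prg3, Ear6, Ear2 and Ear1 had log2 changes of 4.16 ± 1.24, 2.30 ± 0.82, 3.36 ± 1.37 and 3.61 ± 1.55. The peroxidase Epx stood at 5.36 ± 2.67 in naive and 188 ± 361 in tumor eosinophils (adjusted p = 0.604), and major basic protein Prg2 at 1020 ± 11.6 and 7210 ± 11300 (adjusted p = 0.37), so that the spread between tumor libraries exceeded either difference. Of the B and plasma cell list, 0 of 11 members were called by limma (2 higher when adjusted over the list alone). For B and plasma cell genes the median was 0.76 (adjusted p = 0.00543, and adjusted p = 0.483 with an estimated correlation). Examples were Ms4a1, Mzb1 and Cd79a at 2.52, 2.03 and 2.33.

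The other 16 lists were not called in eosinophils (adjusted p = 0.0652 to 0.932), and their members were called as follows. Of the list of eosinophil survival and type 2 signals, 3 of 20 rose and 4 fell (3 and 6 adjusted over the list alone). The interleukin-33 receptor Il1rl1 fell by 2.24 on the log2 scale and Socs2 by 2.86, while Il13ra1 rose by 2.53 and the survival factor Bcl2l1 by 1.87. Alternative activation had 3 of 16 higher and 2 lower (5 and 3), with Clec7a at 3.63 and Retnla at −2.45; its median of −0.48 and its mean of 0.44 differed in sign. Complement and phagocytosis had 4 of 17 higher and 0 lower (5 and 3), with C3 at 2.86. Epithelium had 1 of 20 higher, Reg3g at 2.55, and 3 lower, the absorptive cell genes Slc26a3, Car4 and Car1 at −3.17, −3.18 and −2.40 (5 and 4). Matrix remodelling had 3 of 22 higher and 1 lower (3 and 1), the unfolded protein response 3 of 21 and 0 (4 and 2), angiogenesis 1 of 12 and 1 (1 and 4), hypoxia and glycolysis 1 of 31 and 1 (1 and 1), monocyte 1 of 14 and 0 (4 and 0), resident colonic macrophage 0 of 13 and 1 (0 and 1), and stroma and endothelium 0 of 13 and 1 (0 and 1). Dendritic cell genes had 0 of 7 called by limma (1 and 0), with a median of −0.08 and a mean of 0.45. None of the 5 mast cell, 12 T and NK cell, 5 erythrocyte and 13 mitochondrially encoded members was called by limma, with or without adjustment over the list alone.

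The eosinophil counts rested on 2 naive libraries, whose log2 values had a Pearson r of 0.832 across genes, which are not independent replicates. Without naive library 2, 70 genes were called, 67 of them among the 601, and without naive library 1, 869, with 365 among the 601. Among the tumor libraries, 1 to 3 had 6050 to 6270 CPM of epithelial genes and 25.11 to 35.15% mitochondrially encoded reads, and 4 to 7 had 2180 to 3210 CPM and 15.19 to 23.95%. Without libraries 4 to 7, 974 genes were called, 401 of them among the 601, and 10 of the 18 list calls and 47 of the 60 named calls were kept. Without libraries 1 to 3, 15 and 52 were kept.

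In tumor macrophages the list of resident colonic macrophages was called lower, with a summed level of 3000 ± 331 CPM in naive and 1510 ± 226 in tumor libraries, and the hypoxia and tumor-associated macrophage lists were called higher. Cd163, the haemoglobin scavenger receptor (chromosome 6, 124304656 to 124330527, GRCm38), fell from 221 ± 70.8 normalised reads (SD, n = 5) to 2.38 ± 0.672 (n = 6). Its log2 change was −6.01 ± 0.25 (SE), with an adjusted p of 2.25e-09 by limma. Lyve1, the hyaluronan receptor, fell from 554 ± 106 to 29.9 ± 13.8 (−4.31 ± 0.32, adjusted p = 9.23e-07). Vegfa (chromosome 17, 46016993 to 46032369) rose from 208 ± 37.4 to 1480 ± 280 (2.82 ± 0.16) and osteopontin Spp1 (chromosome 5, 104435118 to 104441050) from 28.1 ± 8.62 to 464 ± 137 (4 ± 0.23), both with an adjusted p of 5.77e-08. The lineage markers Csf1r, the receptor of the macrophage growth factor, and C1qa stayed at 5120 ± 853 against 5120 ± 731 (adjusted p = 0.989) and at 4430 ± 770 against 4310 ± 529 (adjusted p = 0.913).

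Of 11536 genes tested in macrophages, 979 were called higher and 993 lower in tumors, 1972 in all, and 3505 had an unadjusted p under 0.05. Further genes with the smallest p that rose were Cxcl5 (log2 change 5.14 ± 0.33), the ectoenzyme Cd38 (1.84 ± 0.14), haptoglobin Hp (3.54 ± 0.27), the transglutaminase Tgm2 (2.14 ± 0.16), the citrulline-recycling enzyme Ass1 (2.98 ± 0.23) and the keratin Krt14 (5.23 ± 0.40, from 0.418 ± 0.935 to 47.3 ± 11.3). Their adjusted p-values were 1.99e-07 to 9.23e-07. Further genes that fell were the neurotrophic factor receptor Gfra2 (−3.87 ± 0.21), Emp1 (−1.81 ± 0.11), the growth factor receptor Fgfr1 (−3.20 ± 0.22), Stard8 (−2.40 ± 0.18), the transporter Slco2b1 (−2.91 ± 0.23) and Crip1 (−2.26 ± 0.18). These had adjusted p-values of 5.3e-08 to 1.21e-06. Adgre1 fell from 836 ± 169 to 509 ± 101 (−0.71 ± 0.17, adjusted p = 0.00781, and 0.0799 with the closest libraries averaged) and the fractalkine receptor Cx3cr1 from 1960 ± 217 to 1080 ± 216 (−0.87 ± 0.14, adjusted p = 0.000696). Neither was called with 1 fit over all 4 groups (−0.63 and −0.79; adjusted p = 0.15 and 0.193). For 61 of the 71 called genes that the naming rule gave in macrophages, all 6 tumor libraries lay on 1 side of all 5 naive libraries. Chance gives this to a gene in 0.433% of cases, but here too the genes were chosen by their p.

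**Figure D2:**
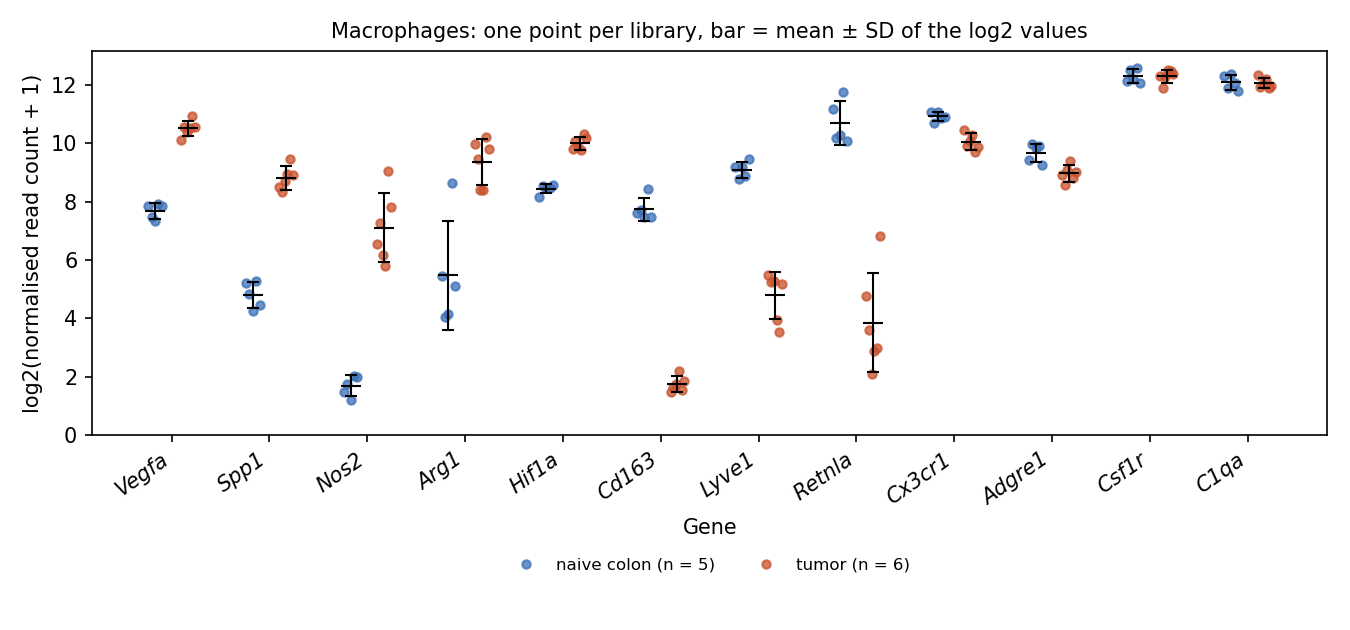
Normalised read counts of 12 genes in macrophages, as log2(value + 1) on the vertical axis, with 1 point per library and bars for the mean and SD of the log2 values (5 naive and 6 tumor libraries). Vegfa, Spp1, Nos2 and Hif1a lie higher and Cd163, Lyve1, Retnla and Cx3cr1 lower in all 6 tumor libraries than in every naive library, while Csf1r and C1qa overlap.

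Of the 18 genes of the resident colonic macrophage list, 14 fell, 0 rose and 4 were not called (16 lower when adjusted over the list alone). For resident colonic macrophage genes the median was −1.22 (adjusted p = 1.86e-14, and adjusted p = 0.0127 with an estimated correlation). Besides Cd163 and Lyve1 they included the lectin Cd209f (−5.28 ± 0.49) and Cd4 (−2.12 ± 0.23), which long-lived gut macrophages carry. Of the hypoxia and glycolysis list, 19 of 31 members rose, 0 fell and 12 were not called, the same when adjusted over the list alone. For hypoxia and glycolysis genes the median was 0.80 (adjusted p = 2.99e-12, and adjusted p = 0.0354 with an estimated correlation). The oxygen-regulated transcription factor Hif1a rose from 349 ± 37.1 to 1040 ± 160 (1.56 ± 0.13), the mitophagy receptor Bnip3 by 1.69 ± 0.16 and the oxygen sensor Egln3 by 2.50 ± 0.24. Of the tumor-associated macrophage list, 13 of 20 members rose, 0 fell and 7 were not called (14 higher and 1 lower when adjusted over the list alone). For tumor-associated macrophage genes the median was 1.21 (adjusted p = 2.21e-11, and adjusted p = 0.0357 with an estimated correlation). Examples were Fabp5 at 2.01 ± 0.17 and cathepsin D, Ctsd, at 1.49 ± 0.13. These were the 3 lists whose calls held with an estimated correlation.

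Inflammatory and interferon genes rose in part. Of the interferon-gamma response list, 16 of 28 members rose, 2 fell and 10 were not called (18 and 2 adjusted over the list alone). For interferon-gamma response genes the median was 0.99 (adjusted p = 4.76e-05, and adjusted p = 0.411 with an estimated correlation). Nos2 rose from 2.32 ± 0.798 to 187 ± 177 (5.42 ± 0.47) and Gbp2 by 1.79 ± 0.27, and Gbp2b changed by −2.72 ± 0.24. Of the neutrophil list, 6 of 11 members rose, 0 fell and 5 were not called (7 and 0 adjusted over the list alone). For neutrophil genes the median was 2.07 (adjusted p = 1.93e-05, and adjusted p = 0.224 with an estimated correlation). Foremost were Lcn2 (4.51 ± 0.49), Ltf (4.11 ± 0.51), S100a9 (5.04 ± 0.75) and S100a8 (4.40 ± 0.75). Of the NF-kB and TNF list, 10 of 28 members rose, 3 fell and 15 were not called (14 and 6 adjusted over the list alone). For NF-kB and TNF genes the median was 0.51 (adjusted p = 0.0194, and adjusted p = 0.712 with an estimated correlation). Examples were the superoxide dismutase Sod2 at 1.48 ± 0.23, the cytokine genes Il1a and Il23a at 1.89 ± 0.31 and 2.88 ± 0.49 and the prostaglandin synthase Ptgs2 at 2 ± 0.35. The list was not called without naive library 5 (median 0.47, adjusted p = 0.0702). Of the immune checkpoint list, 8 of 18 members rose, 1 fell and 9 were not called (10 and 2 adjusted over the list alone). For immune checkpoint genes the median was 0.52 (adjusted p = 0.000964, and adjusted p = 0.242 with an estimated correlation). Examples were the adenosine-producing Nt5e (2.54 ± 0.25), the tryptophan-degrading Ido1 (3.49 ± 0.53), Arg1 (3.89 ± 0.66) and Pilra (0.60 ± 0.11), the last not called with 1 fit over all 4 groups (0.68, adjusted p = 0.0743).

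Part of the matrix remodelling, angiogenesis, and lipid and lysosome lists rose too. Of the matrix remodelling list, 8 of 21 members rose, 1 fell and 12 were not called (9 and 1 adjusted over the list alone). For matrix remodelling genes the median was 0.45 (adjusted p = 0.00105, and adjusted p = 0.224 with an estimated correlation). Examples were the metalloproteinases Mmp10, Mmp14, Mmp12 and Mmp2 at 4.01 ± 0.32, 1.75 ± 0.19, 1.35 ± 0.24 and 0.77 ± 0.15. Of the angiogenesis list, 5 of 12 members rose, 1 fell and 6 were not called, the same when adjusted over the list alone. For angiogenesis genes the median was 0.05 (adjusted p = 0.018, and adjusted p = 0.316 with an estimated correlation). Examples were Thbs1 at 2.61 ± 0.27 and Angpt2 at 1.74 ± 0.31 beside Vegfa and Spp1. Of the lipid and lysosome list, 6 of 23 members rose, 2 fell and 15 were not called (8 and 3 adjusted over the list alone). For lipid and lysosome genes the median was 0.25 (adjusted p = 0.00601, and adjusted p = 0.347 with an estimated correlation). Examples were Abca1 at 1.26 ± 0.16 and Ctsz at 0.83 ± 0.11. Of the oxidative phosphorylation list, 2 of 33 members rose, Atp5b (0.46 ± 0.12) and Cox5a (0.47 ± 0.13), and 31 were not called, the same when adjusted over the list alone (median 0.14; adjusted p = 0.0311, and adjusted p = 0.542 with an estimated correlation). Without naive library 2 or 4 or tumor library 1 that list was not called (medians 0.06, 0.09 and 0.10; adjusted p = 0.148, 0.0856 and 0.0531), nor was Cox5a without naive library 2 (0.39, adjusted p = 0.0512). Atp5b and Cox5a were not called without tumor libraries 5 and 6 (0.39 and 0.44) or with the closest libraries averaged (0.42 and 0.45). With 1 fit over all 4 groups they were not called either (0.54 and 0.55), nor were Mmp12, Mmp2 and Angpt2 (1.43, 0.86 and 1.85; adjusted p = 0.0533 to 0.373 for the 5).

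MHC class II, dendritic cell and immediate-early lists were called lower in tumor macrophages. Of the MHC class II list, 9 of 14 members fell, 2 rose and 3 were not called (10 and 3 adjusted over the list alone). For MHC class II genes the median was −0.69 (adjusted p = 0.0114, and adjusted p = 0.316 with an estimated correlation). H2-DMa changed by −0.89 ± 0.14, H2-Eb1 by −0.78 ± 0.17 and the transactivator Ciita by −0.70 ± 0.17, and the co-stimulatory Cd40 rose by 1.08 ± 0.26. With the closest libraries averaged, H2-Eb1, Ciita and Cd40 were not called (−0.81, −0.69 and 1.10; adjusted p = 0.114, 0.0753 and 0.0516), nor was H2-Eb1 without tumor libraries 5 and 6 (−0.69, adjusted p = 0.0556). Of the dendritic cell list, 7 of 12 members fell, 0 rose and 5 were not called (9 lower and 1 higher when adjusted over the list alone). For dendritic cell genes the median was −1.23 (adjusted p = 0.000103, and adjusted p = 0.347 with an estimated correlation). Examples were Cd209a, Xcr1, Batf3 and Flt3 at −4.40 ± 0.40, −2.08 ± 0.30, −1.28 ± 0.21 and −1.66 ± 0.31. The summed level of dendritic cell genes was 1280 ± 275 CPM in naive and 1410 ± 108 in tumor macrophages, so the total was not lower. Of the immediate-early and dissociation list, 13 of 24 members fell, 1 rose and 10 were not called (19 and 1 adjusted over the list alone). For immediate-early and dissociation genes the median was −1 (adjusted p = 1.2e-08, and adjusted p = 0.224 with an estimated correlation). Examples were Fosb, Egr1, Jund and Ier2 at −1.32 ± 0.19, −1.11 ± 0.17, −1.47 ± 0.24 and −0.96 ± 0.16. Part of the stroma list and the erythrocyte genes fell with them. Of the stroma and endothelium list, 6 of 12 members fell, 0 rose and 6 were not called (8 lower when adjusted over the list alone). For stroma and endothelium genes the median was −1 (adjusted p = 0.000368, and adjusted p = 0.347 with an estimated correlation). Examples were Lum, Col3a1, Acta2 and Dcn at −3.12, −1.71, −1.38 and −1.18. All 4 measured erythrocyte genes fell, Hba-a2, Hba-a1, Hbb-bt and Hbb-bs by 2.25, 2.34, 2.15 and 1.97 on the log2 scale (median −2.20; adjusted p = 0.00556, and adjusted p = 0.368 with an estimated correlation). Naive library 5 had 4830 CPM of erythrocyte genes, against 273 to 941 in the other naive and 127 to 524 in the tumor libraries, and 3820 of stroma genes, against 805 to 1280 and 399 to 952. Without it the erythrocyte list in macrophages (median −1.54, adjusted p = 0.00589) and the stroma and endothelium list in macrophages (−0.70, adjusted p = 0.00152) were still called. In 1-library checks, Acta2 missed the threshold without tumor library 5 or 6 (−1.19 and −1.26; adjusted p = 0.0539 and 0.0514). Dcn (−0.79 to −1.20), Hbb-bt (−1.90 to −2.18) and Hbb-bs (−1.81 to −1.98) did so without 5, 5 and 6 of the single libraries (adjusted p = 0.0513 to 0.0798). With the closest libraries averaged or without tumor libraries 5 and 6, none of Acta2, Dcn and the 4 erythrocyte genes was called (adjusted p = 0.0781 to 0.194). Batf3, Flt3, Acta2, Dcn, Ciita and Cd40 were not called with 1 fit over all 4 groups (−1.21, −1.58, −1.30, −1.10, −0.62 and 1.16; adjusted p = 0.0683 to 0.153). The mitochondrially encoded list had a median of −0.39 with 0 of 13 members called by limma, also when adjusted over the list alone (adjusted p = 0.0157, and adjusted p = 0.524 with an estimated correlation). It was not called without naive library 5 (−0.30, adjusted p = 0.0702).

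The other 16 lists tested in macrophages were not called (adjusted p = 0.0915 to 0.824). Chemokines and cytokines went both ways, with 11 of 29 higher and 7 lower (14 and 10 adjusted over the list alone): the interleukin-1 antagonist Il1rn rose by 2.56 and Osm by 1.90, and the monocyte chemoattractants Ccl7 and Ccl2 changed by −2.68 and −2.44. So did alternative activation, with 6 of 19 higher and 7 lower (7 and 7), where Tgm2 rose and Retnla changed by −6.85 ± 0.65 and Mgl2 by −1.60; its median of 0.13 and its mean of −0.30 differed in sign. Monocyte genes had 5 of 14 higher and 3 lower (6 and 3), with Thbs1 and Ly6a higher and F13a1 and Ccr2 lower. Macrophage identity had 1 of 19 higher and 6 lower (3 and 6), among the latter the mannose receptor Mrc1 (−1.17). Complement and phagocytosis had 3 of 22 higher and 5 lower (5 and 5), with C3 at 1.80 and the scavenger receptor Cd36 at −2.29. The unfolded protein response had 4 of 20 higher and 3 lower (4 and 3), with the cystine carrier Slc7a11 at 3.58 and Atf3 at −1.23. Epithelium had 6 of 19 higher and 3 lower (7 and 5), with a median of 0.75 and a mean of −0.02; Reg3g stood at 2.62 and Car4 at −4.81. Type I interferon genes had 4 of 24 higher and 1 lower (4 and 2), type 2 signals 4 of 20 and 2 (9 and 2), mast cell 2 of 5 and 0 (2 and 0), MHC class I 2 of 16 and 0 (2 and 0), eosinophil identity 2 of 10 and 1 (2 and 1), and T and NK cell 0 of 8 and 1 (0 and 2), that 1 being Cd4. None of the 20 cell cycle, 12 B and plasma cell and 32 ribosomal protein members was called by limma, with or without adjustment over the list alone. Too few granule proteins were measured in macrophages for a test.

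The tumor macrophage libraries lay closest to each other in pairs: libraries 1 and 2, 3 and 4, and 5 and 6 had chi-square values of 9.58, 8 and 13.62 per degree of freedom, against 24.83 to 76.62 for the other pairs, and immunoglobulin shares of 5.13 and 7.52%, 1.05 and 1.05%, and 2.63 and 2.72%. Naive macrophage libraries 2 and 4 (11.96) and 3 and 5 (10.97) lay closest too, against 19.71 to 40.13 for the other naive pairs. Whether such pairs share an animal, a pool or a preparation day is not given in the sources used here. If they do, the p-values over the 5 naive and 6 tumor libraries are too small. When the closest libraries of each group were averaged, leaving 3 against 3, 877 genes were called, 847 of them among the 1972.

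The calls of the 2 cell types overlapped, while the tumor effect on MHC class II genes and Vegfa differed between them. For the 7 MHC class II genes called higher in tumor eosinophils, the rise was 3.52 to 5.73% of the tumor macrophage level. Macrophage-specific transcripts rose by a median of 3.2% of it, so macrophage RNA cannot be told apart from an eosinophil effect there. Among 10855 genes tested in both, 134 were called higher in both, against 24.3 for independent lists, and 77 lower in both, against 21.5. No libraries were shared between the comparisons, but whether the 2 sorts shared animals or digests is not given in the sources used here. Lower in both were Dusp1, Fos, Fosb, Jund, Egr1 and Ier2 of the immediate-early list, for which handling and group cannot be separated. The epithelial genes Car1, Car4 and Slc26a3 were lower in both too. The genes higher in both included the keratins Krt5, Krt6a, Krt6b, Krt13 and Krt14 and the neutrophil list members Lcn2, Ltf, S100a8 and S100a9, named in part after their values were seen. Lrg1, Saa3 and Cxcl5, among the genes with the smallest p in eosinophils, were higher in both as well. Their log2 changes were 4.93, 4.12 and 4.28 in eosinophils and 3.94, 3.5 and 5.14 in macrophages. Whether RNA of other cells present in both tumor sorts gave these 3 rises was not tested. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.39 and a Spearman rho of 0.30. A further 16 genes were called higher in tumor eosinophils and lower in tumor macrophages, among them Ccl2, H2-Aa, H2-Ab1, H2-Eb1, H2-DMa, H2-DMb1 and Cbr2, and 9 lower in eosinophils and higher in macrophages, among them Vegfa, Socs2 and Hvcn1 (named after their values were seen, apart from those the rule gave).

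In the test of the difference itself, the eosinophil effect minus the macrophage effect, 280 genes were called above and 330 below 0 of 15620 tested, 610 in all. Vegfa had a difference of −5.00 ± 0.40 (adjusted p = 7.32e-08), the proton channel Hvcn1 −2.76 ± 0.31 (adjusted p = 1.11e-05) and H2-DMa 3.18 ± 0.33 (adjusted p = 4.5e-06). Cbr2, a carbonyl reductase, had a difference of 6.43 ± 0.60 (adjusted p = 1.2e-06), rising from 163 ± 89.3 to 1160 ± 246 jointly scaled reads in eosinophils and falling from 1570 ± 662 to 151 ± 96.9 in macrophages. The membrane-associated substrate Marcks rose from 53.7 ± 11.8 to 431 ± 174 in eosinophils and stood at 1720 ± 138 and 1490 ± 50.9 in macrophages (3.12 ± 0.34, adjusted p = 7.4e-06). The fitted differences of the adhesion molecule Jaml (6.18 ± 0.47), Scimp (4.75 ± 0.49) and Cd163 (7.81 ± 0.74) depend on the pseudocount, since Jaml and Scimp stood at 0.909 ± 1.28 and 0.862 ± 1.22 in naive eosinophils and Cd163 was at 0 in both of them.

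Of the 34 lists, 15 differed between the cell types. The MHC class II list (8 of 14 members called higher and 0 lower, 10 and 1 adjusted over the list alone; median 2.16; adjusted p = 2.4e-11, and adjusted p = 0.0314 with an estimated correlation) and the resident colonic macrophage list (7 of 18 higher and 0 lower, 10 and 1 adjusted over the list alone; median 2.30; adjusted p = 5.17e-09, and adjusted p = 0.00836 with an estimated correlation) held with an estimated correlation. Of the resident list, Cd163, Cd209f, Cd209g, Folr2 and Timd4 (the last 3 named after their values were seen) fell below the low-value filter in eosinophils. For them the difference rests on the fall in macrophages and on low eosinophil values that depend on the pseudocount. For Cd163 the difference was 7.81, against a change of −6.01 in macrophages. Macrophage RNA in the eosinophil libraries could enter the difference of the MHC class II and macrophage identity lists. It was not told apart there from an effect on the eosinophils. The call of the hypoxia and glycolysis list (0 of 32 higher and 8 lower, 0 and 13 adjusted over the list alone; median −0.68; adjusted p = 7.97e-08) did not hold (adjusted p = 0.067 with an estimated correlation), nor did those of the type I interferon list (8 of 25 higher, 9 adjusted over the list alone; median 1.16; adjusted p = 1.01e-08, and adjusted p = 0.0873 with an estimated correlation) and of the macrophage identity list (10 of 19 higher and 2 lower, 11 and 2 adjusted over the list alone; median 1.46; adjusted p = 5.13e-07, and adjusted p = 0.0674 with an estimated correlation). Ribosomal protein, interferon-gamma, granule protein, dendritic cell, B and plasma cell, chemokine and erythrocyte lists were called higher in eosinophils relative to macrophages, with medians of 0.56, 1.10, 3.64, 1.78, 1.52, 0.60 and 1.41 and adjusted p-values of 0.183 to 0.539 with an estimated correlation. The immediate-early, angiogenesis and type 2 signal lists were called lower, with medians of −0.73, −0.58 and −0.67 and adjusted p-values of 0.502, 0.183 and 0.63 with an estimated correlation. The remaining 19 lists were not called (adjusted p = 0.0551 to 0.903). Median and mean differed in sign for eosinophil identity (−1.12 and 0.46), the unfolded protein response (0.12 and −0.18) and matrix remodelling (0.08 and −0.14). The chemokine list was not called without naive eosinophil library 1 (0.40, adjusted p = 0.189). The erythrocyte and type 2 signal lists were not called with either naive eosinophil library left out (1.78 and 0.74; −0.84 and −0.62; adjusted p = 0.0504 to 0.467). Nor was the erythrocyte list called without tumor eosinophil library 1 or 2, naive macrophage library 5 or tumor macrophage library 6 (0.75 to 1.34; adjusted p = 0.0516 to 0.106). The type 2 signal list was not called without tumor eosinophil library 2 or 3 or naive macrophage library 5 (−0.50, −0.57 and −0.62; adjusted p = 0.0524 to 0.111). Without naive eosinophil library 2, 180 genes were called for the difference, without naive eosinophil library 1, 1877, and without naive macrophage library 3, 406. All 8 named genes were called in each case.

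**Figure D3:**
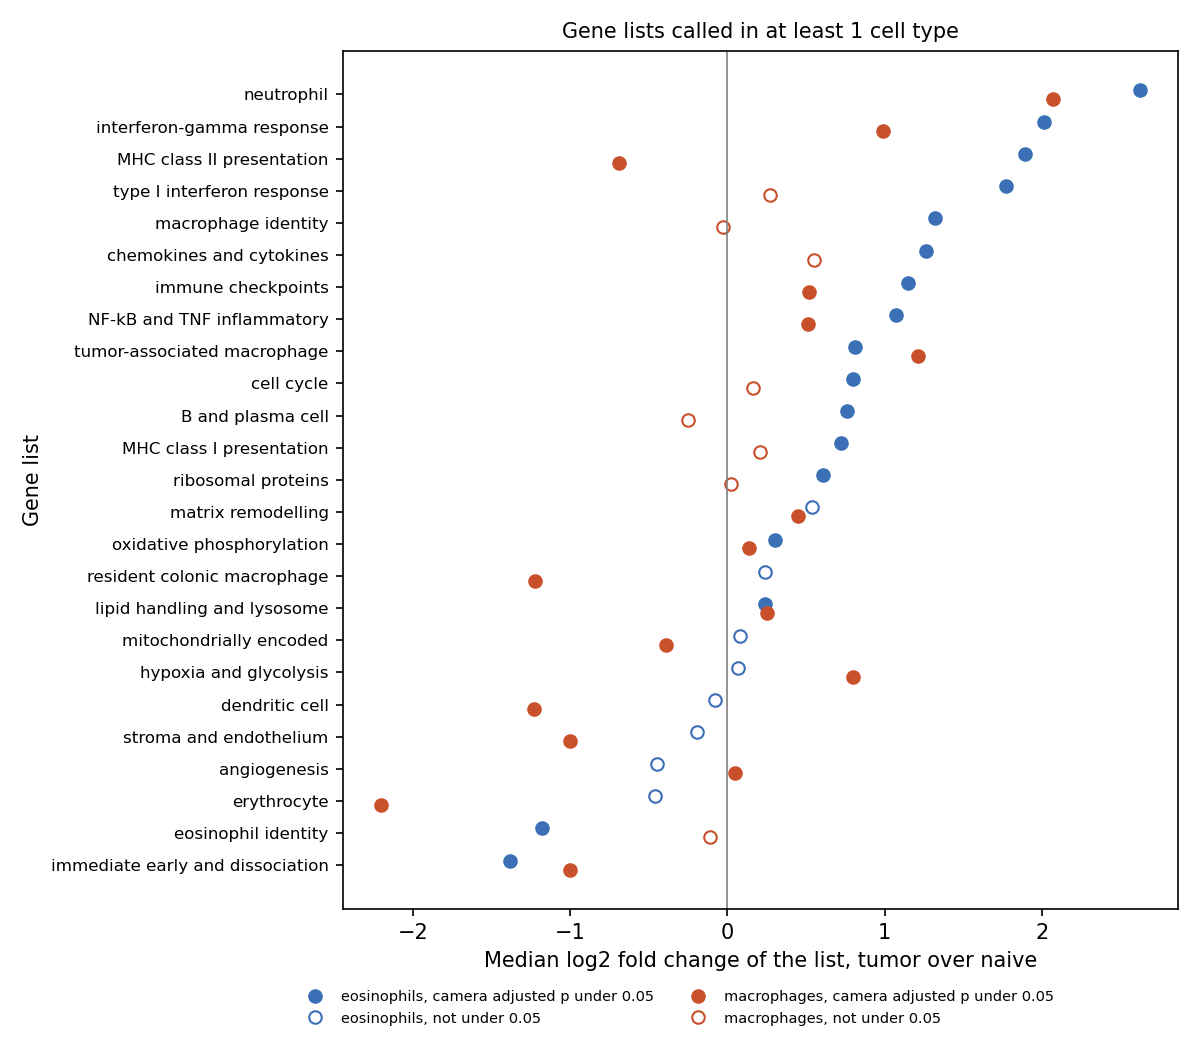
Median log2 change between tumor and naive of the members of 25 gene lists in eosinophils and in macrophages, on the horizontal axis, with filled points for lists with an adjusted p under 0.05 by camera. The MHC class II list lies at 1.89 in eosinophils and −0.69 in macrophages, the resident colonic macrophage list at 0.24 and −1.22, and the immediate-early list at −1.38 and −1.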

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

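The tests of macrophage RNA and the counts of other splits in this part were chosen only after the results were seen. The tumor effect differed between eosinophils and macrophages for 610 genes by a test of the difference itself. Among the 8 named genes the eosinophil effect exceeded the macrophage effect for Cd163 (7.81), Cbr2 (6.43), Jaml (6.18), Scimp (4.75), H2-DMa (3.18) and Marcks (3.12). It lay below it for Vegfa (−5.00) and Hvcn1 (−2.76). H2-DMa was higher in all 7 tumor eosinophil libraries than in both naive ones, and its difference, like that of the other 7, was called without each library in turn. With limma-voom 6 of the 8 were called.

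Some values lay far from the rest of their group. Tumor macrophage library 1 held 2289383 recovered reads (2.289 when counted in units of 10 to the power of 6, against 5.676 to 7.636 in the other 5). The same library had 196 normalised reads of Ndufs1 (269 to 300 in the others) and 49100 of mt-Nd2 (32700 to 37700). Tumor macrophage library 2 had 501 of Ctsd (670 to 793). Naive macrophage library 4 had 2.09 of Krt14 (0 in the others) and 345 of Cd163 (178 to 208). Tumor eosinophil library 2 had 2580 of Cox8a (3460 to 4280). These were 7 of 250 groups of values examined in this way, and about 12.5 would stand apart by chance.

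Of the interferon-gamma response list 10 of 27 and of the MHC class II list 7 of 13 members were called higher in tumor than in naive eosinophils, and RNA of macrophages in the eosinophil libraries is a candidate explanation. For the 10 interferon-gamma members called higher, the rise in tumor eosinophils came to a median of 60.3% of the tumor macrophage level (8.21 to 177%), while 20 abundant macrophage-specific transcripts rose by a median of 3.2% of it (−3.63 to 39.1%, with Apoe at 3.01, C1qb at 5.26, Lyz2 at 2.44 and Cd14 at 19.8). This argues against macrophage RNA for the 7 members above 39.1% and leaves it open for Cxcl9, Gbp3 and Gbp4 (8.21, 27.9 and 33.8%, Gbp4 named after its values were seen). The bound of 39.1% was set by Nlrp3 alone, itself called higher in tumor eosinophils, and Cd14 came next at 19.8%. The other reference transcripts lay at 8.55% or below, so Gbp3 and Gbp4 exceeded all of them but Nlrp3. RNA of epithelium or neutrophils was not tested as a source for the 10 interferon-gamma members. For the 7 MHC class II members the median was 4.15% (3.52 to 5.73%), within the range of the macrophage transcripts, so macrophage RNA and expression by the eosinophils cannot be told apart for them. Of the macrophage identity list, whose members served in part as that reference, 3 of 19 reached 100 CPM in naive eosinophils and 10 stood in another list, and an effect of the tumor on the eosinophils stays open, untested.

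Chance can be excluded for the number of genes called in either cell type only as far as libraries are exchangeable, and the tumor macrophage libraries lie closest in pairs (chi-square per degree of freedom of 8 to 13.62, against 24.83 or more). Naive macrophage libraries 2 and 4 (11.96) and 3 and 5 (10.97) do so too, against 19.71 or more. In eosinophils the real split called 601 genes, 1 of 36 splits of the 9 libraries into 2 and 7 called as many, the real one, which is the smallest share this design can give, and the highest of the others called 11. In macrophages the real split called 1972 genes, 1 of 100 splits (99 drawn from the rest of the 462) called as many, again the real one, and the highest of the others called 143.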

How the results depend on the processing

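The edgeR and TMM fits on recovered reads, the fits without sets of tumor libraries or with the closest libraries averaged, the epithelium covariate, the deposited values of both tables in the interaction, and the factors without mitochondrial and immunoglobulin genes were tests chosen only after the results were seen. In eosinophils 601 genes were called. DESeq2 called 1306 (597 shared), limma-voom 184 (171 shared), 1 fit over all 4 groups 1809 (584 shared), a change of at least 2-fold 36, and the fit without tumor libraries 4 to 7 974 (401 shared). In macrophages 1972 were called, 983 with 1 fit over all 4 groups (834 shared), 240 for at least 2-fold, 1246 without tumor libraries 5 and 6 (1189 shared) and 877 with the closest libraries averaged (847 shared). For the difference 610 were called, 403 without a low-value filter, 1082 with DESeq2, 136 with limma-voom and 36 for at least 2-fold. A 2-fold bound lowers a count by construction, and elsewhere the cause was not tested. Of 60 named genes called in eosinophils 60 were kept with DESeq2, 55 with edgeR, 30 with limma-voom, 59 with 1 fit over all groups and 16 for a change of at least 2-fold. Of 71 in macrophages 71 were kept with edgeR, 70 with limma-voom, 57 with 1 fit and 38 for at least 2-fold. With the epithelium level as covariate 887 and 2237 genes were called, and all 60 and 71 were kept. That covariate differed between tumor and naive by only 0.09 and −0.02 on the log2 scale, so it could hardly move the tumor effects.

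Leaving out single libraries gave 70 (naive 2) to 869 (naive 1) genes in eosinophils, where the lone naive library was assumed to vary like the tumor group, 1514 to 1937 in macrophages, and 180 to 1877 for the difference. In eosinophils 2 pairs are too few to say whether replicate numbers pair the libraries (correlations of 0.13 and 0.12, each library best with its own number). In macrophages they did not (−0.31 to 0.06, none best with its own). With the replicate number as a block, 1130 genes were called in eosinophils (450 shared), 1233 in macrophages and 434 for the difference. The block kept 52 of the 60 named genes and 13 of the 18 list calls in eosinophils, and 61 of the 71 named genes in macrophages. In eosinophils only numbers 1 and 2 occur in both groups. Tumor libraries with other numbers each took a term of their own, so the block fit there rested on 2 pairs and is a weak check. For the difference the block also joined eosinophil and macrophage libraries of the same number, which nothing in the labels pairs. Scaling by library size alone raised the share of higher calls from 52.2 to 66.6% in eosinophils and from 49.6 to 73.8% in macrophages, with the median of all genes at 0.19 and 0.23 on the log2 scale against 0.01 and 0.02. Upper-quartile factors put it at −0.11 in eosinophils and −0.12 for the difference, and RLE factors moved the share of the difference from 45.9 to 61.6% (median 0.07 against −0.06).

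In eosinophils camera called 18 lists, 1 of which was kept with an estimated correlation, and fry, directional, called 10, with 9 of the 18 among them. In macrophages it called 17, of which 3 were kept with an estimated correlation, and fry, mixed, called 28, with 16 of the 17 among them. For the difference it called 15, of which 2 were kept with an estimated correlation and 9 with fry, directional, and fry, mixed, called 23, with 12 of the 15 among them. Reversals touched Csf1r and C1qa in macrophages, which were not called (0 and −0.03). Csf1r was −0.01 with edgeR and with the replicate block, −0.03 without tumor libraries 3 and 4, −0.06 without 5 and 6, and −0.06 to 0.09 over single left-out libraries. C1qa was 0.18 with library size alone, 0.03 with TMM, 0.05 with 1 fit over all groups, 0.04 without tumor libraries 5 and 6, and −0.11 to 0.04 over single left-out libraries.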

Other observations

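The tests of epithelial and neutrophil RNA in this part, the epithelium covariate among them, and the tumor epithelium list, were chosen only after the results were seen. Keratins of squamous type and other tumor epithelial genes (a list of 20, 0 of them in another list) had higher sums in both tumor sorts. In tumor macrophages 19 of 19 tested members rose (median log2 change 3.62), and in tumor eosinophils 6 of 20 rose and 0 fell (median 2.22). Their summed level was 168 ± 23.4 CPM in naive and 1370 ± 669 in tumor eosinophils, and 56.2 ± 22.8 and 756 ± 108 in naive and tumor macrophages. Krt14 rose by 5.23 ± 0.40 in macrophages and Krt6a by 4.30 ± 0.48 in eosinophils.

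Epithelial RNA in the sorted libraries is a candidate explanation for these genes, and if 1 epithelial source fed both sorts, tumor epithelium genes would keep the eosinophil to macrophage ratio of the general epithelium list. The median log2 ratios were 1.18 for the 20 tumor epithelium genes and 1.33 for 19 epithelium genes, a difference of −0.16 (SE 0.33). Single genes, named after their values were seen, ran from −0.93 (Wif1) to 2.43 (Sprr1a) and from −0.24 (Cldn7) to 3.23 (Zg16), with SDs of 0.91 and 0.87. The first SD was narrower than that of most random sets from 953 genes called higher in macrophages (median SD 1.31, 4.14% of 10000 as narrow). Ratios of single genes still lay far apart, so the medians are weak evidence and 1 ratio is not shown. With the epithelium level as covariate, the genes called moved from 601 to 887 and from 1972 to 2237. The 6 and 19 calls were kept, with list medians of 2.02 in eosinophils and 3.61 in macrophages. This covariate, the mean log2 value of the epithelium list, differed between tumor and naive by only 0.09 in eosinophils and −0.02 in macrophages. It could therefore hardly move a tumor effect. The kept calls do not tell whether epithelial RNA, from a changed epithelium or not, was the cause. A sort on haematopoietic markers would remove epithelial cells but not their free RNA, the markers sorted on are not given, and expression by the sorted cells stays open, untested.

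Lcn2, Ltf, S100a8 and S100a9, all members of the neutrophil list, were called higher in both tumor sorts. Neutrophil RNA could give this, since 1 source keeps its genes in 1 ratio between the sorts. The SD of their log2 eosinophil to macrophage ratios was 0.20 (2.16 to 2.64), against a median of 1.68 for 10000 random sets from 134 genes called higher in both, 0.17% of which were as narrow. Retnlg, the most abundant member and named after its values were seen, did not pass the test in eosinophils (−0.35, adjusted p = 0.742), where its high level in naive libraries (27229 and 61287.1 normalised reads) would hide a small share, and of the 16 members 3 reached 100 CPM in naive eosinophils, 1 in naive macrophages and 2 stood in another list. Of the 6 members called higher in each sort, only the 4 called in both entered this SD, which limits what it says of 1 source. The keratins Krt5 and Krt6a (2.42 and 2.40) lay between 2.16 and 2.64 too, while tumor epithelium genes ran from −0.93 to 2.43. The same narrow ratio would come from epithelium that makes these genes, or from a shared response of both cell types, and neither was tested.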
